A study of Mus musculus with 2 samples.

How the data were processed

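H3K4me3 was measured by chromatin immunoprecipitation and sequencing in intestine of mouse embryos at embryonic day 14.5. Both samples belonged to 1 group, with replicate numbers 1 and 2 given by the labels as biological replicates. Replicate 1 was tissue pooled from 24 embryos and replicate 2 from 34, of both sexes. Replicate 2 joined 2 technical replicates, per the labels. No second group was part of the series, so no comparison between groups was made.

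The authors deposited 4 peak lists, 1 per replicate, 1 called on both replicates together and 1 of replicated peaks. Per the text deposited beside the lists, they are in narrowPeak format on mm10 (GRCm38), and the replicated list was derived from the pooled list and the 2 lists of the replicates. Each peak in the deposited lists has a signal value from the authors' peak caller, whose scale is not stated, so it was used only to describe and rank peaks within a list. Each peak also has a −log10 p-value and a −log10 q-value as the authors' caller gave them. The aligner, the peak caller, their versions, their thresholds and the rule that made a peak replicated are not given in the sources used here. The lowest −log10 p was 2.05, 2.09, 2.06 and 2.43 in replicate 1, replicate 2, the pooled and the replicated list, so all 4 hold weak peaks. A −log10 p of 5 or more was reached by 86.1%, 76.0%, 82.2% and 98.2% of them. All 21763 replicated peaks were identical to a pooled peak, 20420 (93.8%) overlapped a peak in each replicate, and 1343 (6.17%) did not. How many reads stand behind a peak is unknown, and a shallower library gives fewer, narrower and more broken peaks at the same locus. How reads that map to several places were treated is not given either, so peaks at near-identical gene copies are uncertain.

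Genes came from GENCODE mouse release 21 and sequence from RefSeq's GRCm38 patch 6. No peak ended beyond any of the 21 assembled chromosomes. Peaks on other scaffolds, 10 to 12 per list, were left out of the comparisons. Of 21938 protein-coding genes on the chromosomes, 85 had no protein-coding transcript and were left out, which left 21853. A gene was marked when a peak overlapped a window of 1 kb either side of the start of any of its protein-coding transcripts. Its signal was the highest of the overlapping peaks. Domains were peaks of a list joined across gaps of up to 1 kb, and a gene's width was that of the widest domain at its starts. Widths per replicate came from that replicate's own list and are given as mean ± SD with n = 2. A CpG-rich promoter had an observed over expected CpG of at least 0.6 and a GC content of at least 50% in 1 kb around a start.

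Peaks of both replicates were called shared from an overlap of 1 bp. Overlap and location were set against 100 circular shifts within chromosomes with a fixed seed. The 24 gene lists (22 spelled out, 2 by symbol pattern) were compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 24 and a threshold of 0.05. List medians of width were placed among 10000 random lists of the same size, drawn with replacement from the other marked genes. All symbols of the lists were found in the annotation, by an older name where needed. Lists overlap in a few members, such as Ptch1 and Gata4.

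The gene lists, their tests of marking and width and most alternatives were fixed before the data were examined. The named genes followed a rule fixed at the same time. It took up to 4 marked members with the widest domains and up to 2 unmarked members, first in list order, from each list not given by a pattern. It added the protein-coding genes under the 15 widest domains and the fixed genes Cdx2, Hnf4a, Foxf1, Acta2, Phox2b, Sox10, Pecam1, Ptprc, Alb, Foxg1, Myod1, Hoxa13 and Hoxd13. It also took the 5 genes marked in both replicates with the largest difference of signal rank, namely Kdm6b, Agrp, Ctcf, Dmac2 and Hmces. Where genes share a start within 1 kb, 1 peak marks both, and the text names the partner.

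Alternatives were windows of 0.5 and 2.5 kb, the annotated 5' end of the gene as the only start, and the pooled list. Others were a −log10 p of at least 5, each replicate's own list in place of the replicated list, and genes with no shared start. Further ones were genes with CpG-rich promoters, merging gaps of 0, 0.5 and 2 kb, and overlap of at least 50% of both or either peak. The last were equal numbers of top-ranked peaks, and width times signal in place of signal. A peak in any of the 4 lists, list medians of signal, 30 gene families and the noncoding RNAs were added after the data had been seen. So were the matching of widths on the number of CpGs, the matching of signal on CpG content and the matching of marking on CpG content for lists other than the enterocyte and brain lists. Marking and width were tested on simulated data with known answers. The simulated genes had a single start each, lay far from other coding starts and were marked without regard to CpG content. Shared starts, clustered genes and CpG effects were thus not part of this check. For 4186 simulated genes all 4 lists with a changed share and none of 16 unchanged lists were called, and both lists with tripled widths and none of 18 unchanged lists fell outside the central range. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.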

Results

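The series profiled H3K4me3 in the intestine of mouse embryos at embryonic day 14.5 by chromatin immunoprecipitation and sequencing. H3K4me3, trimethylation of a lysine near the end of histone H3, is found at the starts of active genes and of genes poised for activity. There was 1 group of 2 biological replicates, each intestine pooled from several embryos, 24 for replicate 1 and 34 for replicate 2. The tissue was whole intestine, so each list mixes epithelium, mesenchyme, muscle, nerve and vessel cells. Replicate 1 had 26128 peaks with a median width of 1079 bp, and replicate 2 had 29216 peaks with a median width of 800 bp. The authors' set called on both replicates together held 28268 peaks, and their replicated set held 21763 peaks with a median width of 1485 bp. The replicated peaks covered 36.0 Mb, 1.32% of the genome. Only peak lists were used here, so the sequencing depth behind each value is unknown and no interval that needs it is given. With no other group, the comparisons set the replicates against each other, lists of genes against all other genes, and regions against shifted peaks.

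Nearly the same genes carried H3K4me3 at their starts in both replicates. Of 21853 protein-coding genes, 14272 were marked in both, among them Cdx2, Foxf1, Shh and Acta2. Only 165 genes were marked in replicate 1 alone and 137 in replicate 2 alone, so 97.9% of the genes marked in either replicate were marked in both. The goblet cell regulator Spdef and the endothelial receptor Tie1 were marked in replicate 1 alone, and Hoxc12 in replicate 2 alone. The mean number of marked genes was 14423 ± 19.8 (SD, n = 2). Of the peaks of replicate 1 on assembled chromosomes, 84.4% overlapped a peak of replicate 2, and 82.2% of the peaks of replicate 2 overlapped a peak of replicate 1. After 100 circular shifts of 1 set within chromosomes, the mean overlap was 2.53% and 2.38%, with highest values of 2.92% and 2.69%. Across the genes marked in both, domain width had a Spearman rho of 0.926 between replicates. Peak signal had a Spearman rho of 0.742 and its log2 value a Pearson r of 0.865. These correlations run across genes, which are not independent replicates, and carry no p-value.

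The genes whose signal rank differed most between replicates included Kdm6b, which encodes a demethylase of histone H3 lysine 27, and Ctcf, which encodes the insulator protein. The signal at Kdm6b stood at percentile 84.9 of marked genes in replicate 1 and at percentile 3.21 in replicate 2, although its domain measured 12.9 ± 0.38 kb (SD, n = 2). Ctcf and Agrp share a start and stood at percentile 94.3 in replicate 1 and 15.02 in replicate 2. Hmces stood at percentile 91.2 and 15.1. Dmac2 went the other way, with percentile 15.03 in replicate 1 and 92.5 in replicate 2. All of them were marked in both replicates.

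Peaks found in a single replicate were narrow, weak and mostly away from promoters. Replicate 1 had 4062 such peaks, 15.6% of its list, with a median width of 248 bp against 1345 bp for its shared peaks. Only 19.4% of them lay at a protein-coding promoter, against 68.6% of the shared peaks. Replicate 2 had 5200, 17.8% of its list, with a median width of 210 bp against 1122 bp, and 16.2% at a promoter against 66.0%. Among named genes, the weak peak at Nkx2-5, a cardiac transcription factor, was called in replicate 1 alone at 294 bp, and that at Tbx5, another one, in replicate 2 alone at 462 bp. Of the single-replicate peaks, 43.3% in replicate 1 and 21.2% in replicate 2 had a −log10 p of 5 or more.

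H3K4me3 lay at 14380 of the 21853 protein-coding genes in the replicated set, 65.8%. The mark was found at 98.8% of the 10943 genes with a CpG-rich promoter and at 32.7% of the other 10910 genes. Peaks within 1 kb of an annotated start made up 75.5% of the replicated peaks and 88.8% of the covered bases, against a mean of 10.5% of peaks after shifting. Each peak was counted once, at a start where possible, then in an exon, then in an intron, and otherwise outside genes. Counted so, exons held 4.46% of all peaks against 9.29% after shifting, introns 8.45% against 31.1%, and regions outside genes 11.5% against 49.1%. These lower shares follow at least in part from the higher share at starts, so they do not show that exons or introns were avoided. In the replicates' own lists, which hold more weak peaks, the share at starts was 69.2% in replicate 1 and 65.9% in replicate 2.

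The 5319 replicated peaks away from any annotated start, 24.5% of the set, had a median width of 631 bp against 1802.5 bp at starts. Their median signal was 5.57 against 28.9, and they lay a median of 14771 bp from the nearest protein-coding start. Of them, 27.3% lay within 5 kb of such a start. Distal here refers to single peaks, and some of these are parts of domains that reach a start once peaks are joined. The widest of them, chosen after their values were seen, measured 5312 bp (chromosome 1, 82282550 to 82287861, GRCm38). It overlapped an annotated exon, and its nearest coding start was that of Irs1, the insulin receptor substrate. Another of 4562 bp overlapped the exon at the 3' end of Nr2f2, which encodes an orphan nuclear receptor. It is 1 of the 5 peaks joined into the domain of 21229 bp at Nr2f2. Some wide distal peaks had a strong signal and lay outside genes. Their nearest coding genes were Hfe2 (4518 bp, signal 46.3) and Olfr1423 (4267 bp, signal 41.3). A narrower peak of 3943 bp with a signal of 14.8, also chosen after the values were seen and not next in width, overlapped an annotated exon. Its middle lay 71408 bp from the nearest coding start, that of Mylk, the myosin light chain kinase of smooth muscle. The full list of replicate 2 held 9973 peaks away from starts and that of replicate 1 held 8044, both over 1.5 times the count in the replicated set.

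Transcription factors and junction genes of the intestinal epithelium were marked at almost every member, while genes of the mature absorptive cell were mostly unmarked. The factors were marked at 20 of 22 genes (90.9% in each replicate, against 65.8% of other genes, adjusted exact p = 0.0160). Domains were 11.8 ± 0.77 kb (SD, n = 2) at Gata6 and 9.19 ± 0.13 kb at Gata4, both of the zinc finger family that patterns endoderm. They were 9.81 ± 1.83 kb at Foxa1, a pioneer factor of endoderm, and 8.76 ± 0.41 kb at Cdx2, which specifies intestinal identity. Hnf4a, a nuclear receptor of the epithelium, had a domain of 2.17 ± 0.17 kb, and Creb3l3 and Ehf were unmarked. The junction and cytoskeleton genes were marked at 19 of 20 (95% in each replicate, adjusted exact p = 0.00608). They included Ezr, which encodes the microvillus linker ezrin, at 5.79 ± 0.039 kb, Cldn3, a tight junction claudin, at 3.72 ± 0.40 kb, Epcam at 3.27 ± 0.035 kb and Cdh1, the epithelial cadherin, at 2.83 ± 0.53 kb. Cldn2 was unmarked.

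Absorptive enterocyte genes were marked at 7 of 22 (31.8% in each replicate, adjusted exact p = 0.00237), less often than other genes. The lactase gene Lct and the sucrase gene Sis had no peak in either replicate. The marked members included Dpp4, a brush border peptidase, at 2.00 ± 0.048 kb, Anpep, another, at 1.65 ± 0.087 kb, and Apob, the chylomicron apolipoprotein, at 1.02 ± 0.063 kb. Mttp, which loads lipid onto Apob, measured 2.58 ± 0.14 kb but shares its start with Trmt10a. Of the 22 members, 1 had a CpG-rich promoter. Secretory and enteroendocrine genes were marked at 14 of 25 (64.0% and 56.0% in replicates 1 and 2, adjusted exact p = 0.312), which did not pass the test. Isl1 measured 5.65 ± 1.03 kb, Gfi1 4.85 ± 1.20 kb, Insm1 3.88 ± 0.71 kb and Nkx2-2 2.89 ± 1.07 kb, all transcription factors of secretory or endocrine precursors, while the mucin gene Muc2 and Spdef were unmarked. Wnt and stem cell genes were marked at 23 of 24 (95.8% in each replicate, adjusted exact p = 0.00171). Rnf43, a brake on Wnt receptors, measured 6.39 ± 0.088 kb, Lrig1 6.29 ± 0.25 kb, Myc 6.01 ± 0.14 kb and Sox9 5.77 ± 0.73 kb, and only the crypt marker Olfm4 was unmarked.

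All 30 gut mesenchyme genes carried the mark in the replicated set and in each replicate (adjusted exact p = 2.36e-05). Their domains were among the widest of the tissue, with 22.5 ± 1.78 kb (SD, n = 2) at Meis2 and 15.6 ± 0.086 kb at Meis1, homeobox cofactors of Hox proteins, and 19.3 ± 0.34 kb at Ptch1, the Hedgehog receptor. Foxf1 measured 13.3 ± 0.59 kb and Foxf2 11.7 ± 4.88 kb, both forkhead factors that respond to Hedgehog in gut mesenchyme. The domain at Foxf2 was 15177 bp in replicate 1 and 8279 bp in replicate 2. Smooth muscle genes were marked at 15 of 18 (88.9% and 83.3%, adjusted exact p = 0.153), which did not pass the test. Chrm2, a muscarinic receptor, measured 5.44 ± 0.39 kb, Srf, the serum response factor, 4.77 ± 0.25 kb, Tpm2, a tropomyosin, 4.35 ± 1.37 kb, and Smtn 3.45 ± 1.5 kb. Acta2, smooth muscle actin, measured 3.81 ± 0.35 kb, and Kcnmb1 and Ldb3 were unmarked.

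Genes of the enteric nervous system, vessels and mesothelium were mostly marked, but none of the 3 lists passed the test. Enteric nervous system genes were marked at 21 of 25 (88.0% and 80.0%, adjusted exact p = 0.0706). Hand2, a transcription factor of enteric neurons and mesenchyme, measured 13.6 ± 0.63 kb (SD, n = 2), Ednrb, the endothelin receptor of crest cells, 5.28 ± 1.36 kb, and Gfra1, the GDNF co-receptor, 4.93 ± 1.71 kb. Phox2b, needed for all enteric neurons, measured 4.67 ± 1.07 kb, and Sox10, a crest factor, 1.64 ± 1.16 kb. At Foxd3 the domain was 10472 bp in replicate 1 and 2492 bp in replicate 2. Plp1 and the neuropeptide gene Vip were unmarked. Endothelial genes were marked at 19 of 22 (95.5% and 90.9%, adjusted exact p = 0.0552), with 5.71 ± 1.25 kb at Ets1, 4.58 ± 0.84 kb at Fli1, 4.5 ± 1.48 kb at Egfl7 and 4.09 ± 0.22 kb at Esam. Pecam1, an endothelial adhesion molecule, measured 1.94 ± 0.61 kb at a start shared with Milr1. Tie1 and Nos3 were unmarked in the replicated set, although Nos3, the endothelial nitric oxide synthase, had a weak peak in each replicate's own list. The endothelial call was passed in either replicate's own list (adjusted exact p = 0.00387 and 0.0161) and the enteric call only in that of replicate 1 (adjusted exact p = 0.0234 against 0.222). Mesothelial genes were marked at 9 of 13 (69.2% in each replicate, adjusted exact p = 1). Wt1, a mesothelial transcription factor, measured 4.84 ± 1.53 kb, Podxl 4.41 ± 0.29 kb, Aldh1a2, a retinoic acid synthase, 3.80 ± 0.098 kb and Krt19 2.51 ± 0.22 kb, while Msln and Upk1b were unmarked.

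Blood, liver, stomach, heart, skeletal muscle and germline genes were marked less often than other genes, and pancreas genes did not differ by the test. Against lists matched on CpG content, a comparison made after the data had been seen, only stomach and germline genes stayed low. Blood, liver, cardiac and skeletal muscle genes did not, so CpG content stays open for their calls. Blood and immune genes were marked at 7 of 25 (28.0% and 32.0%, adjusted exact p = 0.000374). Among them the hematopoietic factors Runx1 measured 5.13 ± 0.40 kb (SD, n = 2), Tal1 3.87 ± 0.73 kb and Ikzf1 2.21 ± 0.10 kb, and the erythropoietin receptor Epor 1.69 ± 0.12 kb. The leukocyte gene Ptprc and the myeloid factor Spi1 were unmarked. Liver genes were marked at 5 of 20 (25% in each replicate, adjusted exact p = 0.000502). Albumin, Alb, and alpha-fetoprotein, Afp, were unmarked, while Cebpa measured 4.77 ± 0.018 kb, Hhex 2.90 ± 0.67 kb and transthyretin, Ttr, 1.26 ± 0.30 kb. Apoh measured 2.97 ± 0.012 kb at a start shared with Prkca, and the fifth marked member was Trf. Stomach genes were marked at 1 of 16 (adjusted exact p = 7.29e-06), namely Sox2, a factor of foregut and neural cells, at 2.65 ± 0.61 kb. Gkn1 and Gkn2 were unmarked. Pancreas genes were marked at 8 of 17 (47.1% in each replicate, adjusted exact p = 0.143). Mnx1 measured 3.67 ± 0.56 kb, Nkx6-1 2.68 ± 0.20 kb, Pdx1, a factor of pancreas and duodenum, 2.14 ± 0.76 kb and Mafa 1.83 ± 0.30 kb, and the insulin genes Ins1 and Ins2 were unmarked.

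Cardiac genes were marked at 7 of 20 (40.0% and 45.0%, adjusted exact p = 0.0105). They included Gata4, Ryr2 at 1.95 ± 0.093 kb (SD, n = 2), Myl3 at a start shared with Pth1r, 3.37 ± 0.41 kb, and Myl4 at a start shared with Cdc27, 2.44 ± 0.18 kb. The cardiac call ended with the full list of replicate 2 (adjusted exact p = 0.0743), with the pooled set (50% marked, adjusted exact p = 0.165) and with a window of 2.5 kb (50%, adjusted exact p = 0.173). Skeletal muscle genes were marked at 6 of 20 (30.0% and 25%, adjusted exact p = 0.00240). Myod1, the myogenic regulator, measured 0.65 ± 0.13 kb and Ryr1, the calcium release channel, 0.74 ± 0.18 kb. Mylpf measured 3.87 ± 0.53 kb at a start shared with Tbc1d10b and Actn3 1.80 ± 0.22 kb at a start shared with Zdhhc24, and Myf5 and Myf6 were unmarked. The skeletal call ended with a window of 2.5 kb (45.0%, adjusted exact p = 0.0773). Germline genes were marked at 4 of 20 (15% in each replicate, adjusted exact p = 0.000107), namely Boll at 1.02 ± 0.21 kb, Dazl at 0.81 ± 0.093 kb, Dppa3 in replicate 1 only and Tdrd1 in replicate 2 only. The germ cell helicase Ddx4 and the synaptonemal gene Sycp1 were unmarked. Olfactory receptor genes were marked at 3 of 1134, namely Olfr1033, Olfr658 and Olfr94, named after their values were seen, and the p-value was too small for the computer to hold. Their marking was not set against lists matched on CpG content, so CpG content stays open for this call.

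Developmental genes of the brain were marked in the intestine more often than other genes, at 23 of 25 (88.0% and 92.0%, adjusted exact p = 0.00739). Dlx1 measured 4.54 ± 1.87 kb (SD, n = 2), Dlx2 4.21 ± 0.27 kb, Emx1 2.53 ± 0.34 kb and Neurog2 2.22 ± 0.086 kb, all forebrain transcription factors. Foxg1, which specifies the telencephalon, had a narrow domain of 1.14 ± 0.038 kb, and Otx2 and Neurod6 were unmarked, although the pooled list had a peak at Otx2. When only the annotated 5' end of the gene was taken as the start, 18 of 25 were marked and the call ended (72.0%, adjusted exact p = 0.429). Hox genes were marked at 38 of 39 (97.4% and 100%, adjusted exact p = 1.69e-05), the exception being Hoxc12. Genes of posterior identity were among them, with 3.16 ± 1.17 kb at Hoxa13 and 1.84 ± 0.63 kb at Hoxd13.

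Signalling, proliferation and housekeeping genes were marked throughout. All 34 Hedgehog, BMP and Notch pathway genes carried the mark in both replicates (adjusted exact p = 7.29e-06), with 10.4 ± 0.52 kb (SD, n = 2) at Shh, the ligand made by gut epithelium, 8.95 ± 0.12 kb at the BMP target Id2 and 8.33 ± 0.076 kb at the Notch target Hes1. All 25 cell cycle genes were marked (adjusted exact p = 0.000138), with 7.99 ± 0.045 kb at Ccnd2 and 6.2 ± 0.059 kb at Ccnd1, which encode D-type cyclins, 4.13 ± 0.25 kb at Pcna and 3.94 ± 0.27 kb at Rrm2. All 28 housekeeping genes were marked (adjusted exact p = 3.43e-05), with 7.90 ± 0.13 kb at Rpl13a, 6.17 ± 0.15 kb at Ywhaz, and 4.81 ± 2.47 kb at Rps18 and 4.44 ± 0.22 kb at Tbp, whose starts are shared with Vps52 and Psmb1. Ribosomal protein genes were marked at 73 of 76 (adjusted exact p = 2.56e-09). The unmarked members, named after their values were seen, were Rpl10l, Rpl39l and Rpl3l.

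Of the 24 lists, 10 were marked more often and 8 less often than other genes, and 6 did not pass Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists. The test describes genes of these peak lists and not replicates. Among the genes with a CpG-rich promoter alone, 98.8% of other genes were marked and no list was marked more often. Of the lists compared there, only the germline list stayed less often marked (3 of 8, adjusted exact p = 3.44e-07). Several other lists kept few members on that background, and the olfactory receptor list was not compared on it.

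**Figure D1:**
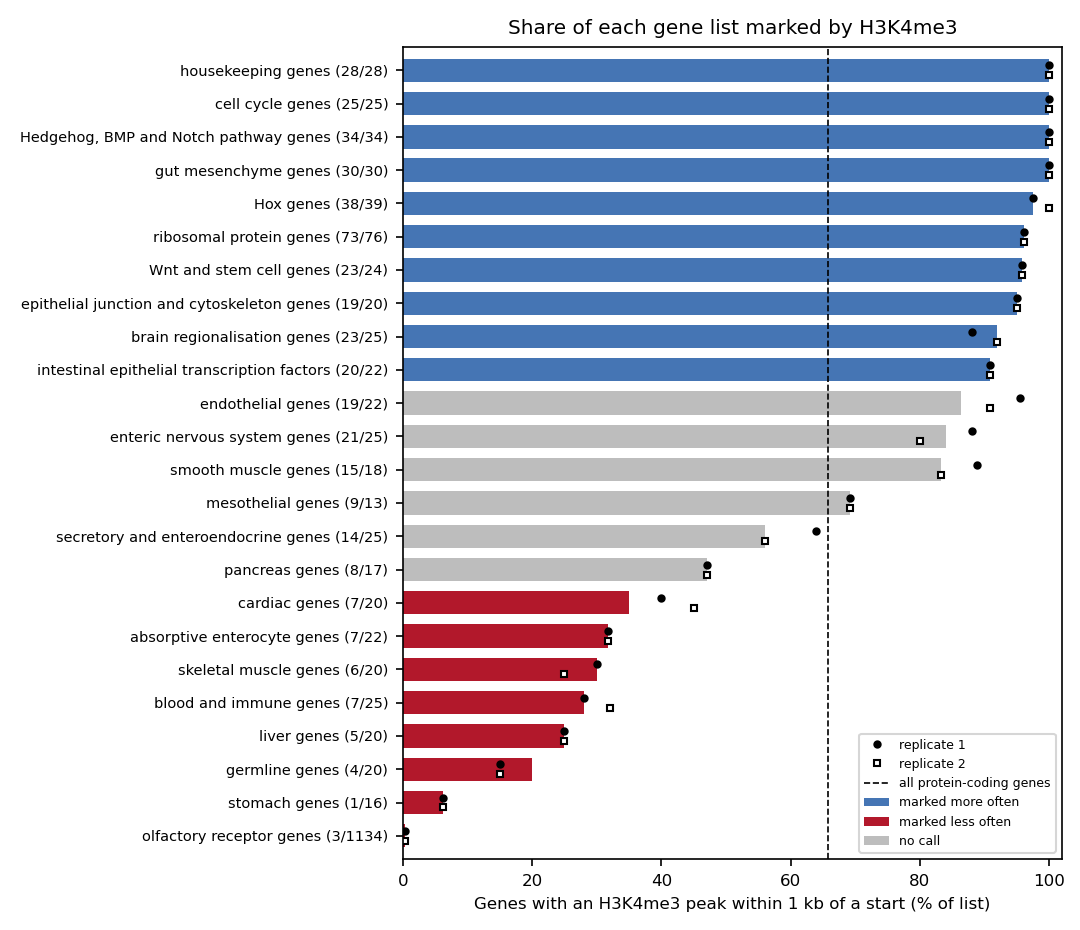
Bars show the percentage of each gene list with a replicated H3K4me3 peak within 1 kb of a start, coloured by the call, with a dot for replicate 1, a square for replicate 2 and a dashed line at 65.8% for all protein-coding genes. All 30 gut mesenchyme genes were marked, against 7 of 22 absorptive enterocyte genes and 3 of 1134 olfactory receptor genes.

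Domains were wider than over other marked genes for 9 lists. The median domain was 6338 bp over marked Hox genes, 5943 bp over gut mesenchyme genes, 5025.5 bp over intestinal epithelial transcription factors and 4553.5 bp over Hedgehog, BMP and Notch genes. Over other marked genes the median was between 2113 and 2119 bp, so these medians were 2.997, 2.81, 2.38 and 2.15 times as wide. The Hox value depended on how peaks were joined, and its place above the other 3 did not hold. With peaks left unmerged its median was 3750.5 bp (1.85 times), below the 4489.5 bp of epithelial transcription factors, 4089.5 bp of mesenchyme and 3892.5 bp of Hedgehog, BMP and Notch genes. With gaps of up to 2 kb joined it was 15081 bp (7.01 times), and in replicate 2 it was 4051 bp (2.07 times), again below the other 3. Smooth muscle genes had a median of 4136 bp and Wnt and stem cell genes of 3224 bp. Housekeeping genes at 3084.5 bp, ribosomal protein genes at 2838 bp and cell cycle genes at 2768 bp were also wider, and all 9 lists were wider in both replicates, with peaks left unmerged and with a gap of 2 kb. Domains were narrower over absorptive enterocyte genes at 1260 bp, germline genes at 787.5 bp, skeletal muscle genes at 876.5 bp, brain regionalisation genes at 1682 bp and the 3 marked olfactory receptor genes at 371 bp.

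Each median was called wider or narrower where it lay outside the central 95% of 10000 random lists of the same size drawn from the other marked genes. The remaining 9 of the 23 lists compared lay inside, with medians of 2518 bp for liver, 2494 bp for junction and cytoskeleton, 2448 bp for enteric nervous system, 2401 bp for endothelial, 2318 bp for mesothelial, 1996 bp for cardiac, 1803 bp for blood and immune, 1758 bp for secretory and enteroendocrine and 1749.5 bp for pancreas genes. The secretory list did not stay inside, and was narrower with unmerged peaks (973 bp, 0.478 times, percentile 0), a gap of 0.5 kb (percentile 0.515), the pooled set (percentile 0.29) and the full list of replicate 1 (percentile 0.01). Not all of the others stayed inside either. With the pooled set blood and cardiac genes became narrower, and enteric nervous system and junction genes wider. With a gap of 2 kb enteric nervous system genes became wider too. The stomach list had 1 marked member and was not compared. The calls over brain and skeletal muscle genes ended with the pooled set and in replicate 2, where the medians were 1853 and 1644 bp against 1956 bp over other genes. The brain call also ended with a gap of 2 kb (1765 bp against 2155 bp, 0.819 times, percentile 3.87). Among genes with CpG-rich promoters 7 of the 9 lists stayed wider. The call ended over smooth muscle genes, of which 3 members were left (0.691 times the median of other genes, percentile 6.235), and over cell cycle genes (1.22 times, percentile 97.375). Junction, endothelial, mesothelial and blood genes became wider there, so that 11 lists were wider in all.

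**Figure D2:**
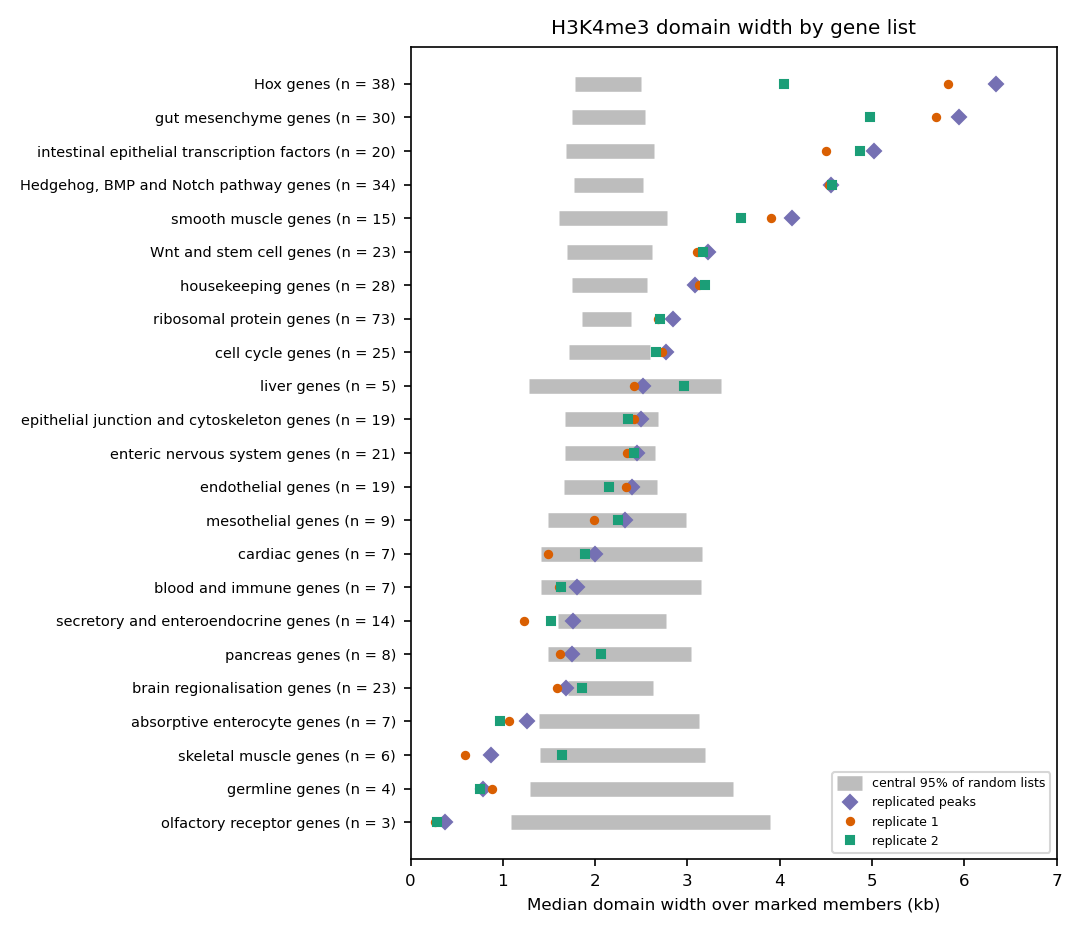
Diamonds show the median domain width in kb over the marked members of each list in the replicated peaks, with circles for replicate 1, squares for replicate 2 and grey bars for the central 95% of random lists of the same size. The medians of the Hox, gut mesenchyme and epithelial transcription factor lists lie above 5 kb, and that of the absorptive enterocyte list lies at 1260 bp.

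Hox genes lay under 4 of the 15 widest domains. The widest, of 32090 bp, ran over Hoxb3, Hoxb4, Hoxb5 and Hoxb6, with 32.3 ± 0.37 kb (SD, n = 2) in the replicates. The next covered Hoxa1, Hoxa2 and 5730596B20Rik over 24096 bp, and 17862 bp covered Hoxa3, Gm28308, Hoxa5 and Hoxa6. Replicate 2 gave 14589 bp there, while replicate 1 gave 10874 bp at Hoxa5 and a separate 5862 bp at Hoxa3, Gm28308 and Hoxa6. Hoxa10 stood under a domain of 12437 bp that measured 7.36 ± 0.76 kb in the replicates. Nr2f2 had 20.9 ± 0.36 kb, Tbx2, a T-box repressor, 15.5 ± 0.022 kb, and Zfp503, a zinc finger repressor, 12.2 ± 2.57 kb. Mab21l2, which lies within Lrba, had 15.2 ± 1.80 kb, Bahcc1 12.8 ± 0.31 kb and Kdm6b 12.9 ± 0.38 kb. The others were Meis2, Ptch1, Foxf2, Meis1 and Foxf1. Of 19611 domains, 466 (2.38%) were wider than 5 kb and 30 wider than 10 kb, against a median of 1672 bp. With peaks left unmerged, 8 of the 15 stayed among the widest.

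**Figure D3:**
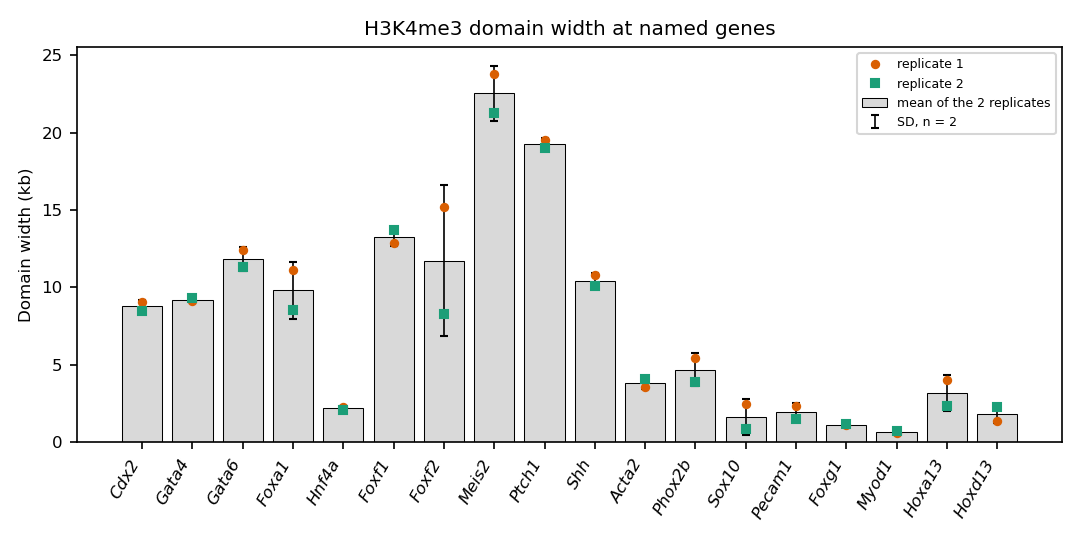
Bars show the mean domain width in kb at 18 named genes over the 2 replicates, with the SD as error bars, circles for replicate 1 and squares for replicate 2. Meis2 (22.5 kb) and Ptch1 (19.3 kb) stand highest, and Foxg1 (1.14 kb) and Myod1 (0.65 kb) lowest.

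The Hoxb cluster carried the mark from Hoxb9 to Hoxb1 in 23 replicated peaks, between 96256457 and 96383256 on chromosome 11 (GRCm38). The widest domain, 96298510 to 96330599, began inside the span of Hoxb6, within 1 kb of a protein-coding start of that gene, and ended inside Hoxb3. Hoxb5 and Hoxb4 lay fully under it. At the Foxf1 locus on chromosome 8, a domain from 121078034 to 121091134 covered the whole of Foxf1 (121084386 to 121088144) and the start of Fendrr, a noncoding RNA transcribed away from it. Separate peaks covered the starts of Mthfsd and of Foxc2, another forkhead factor.

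**Figure D4:**
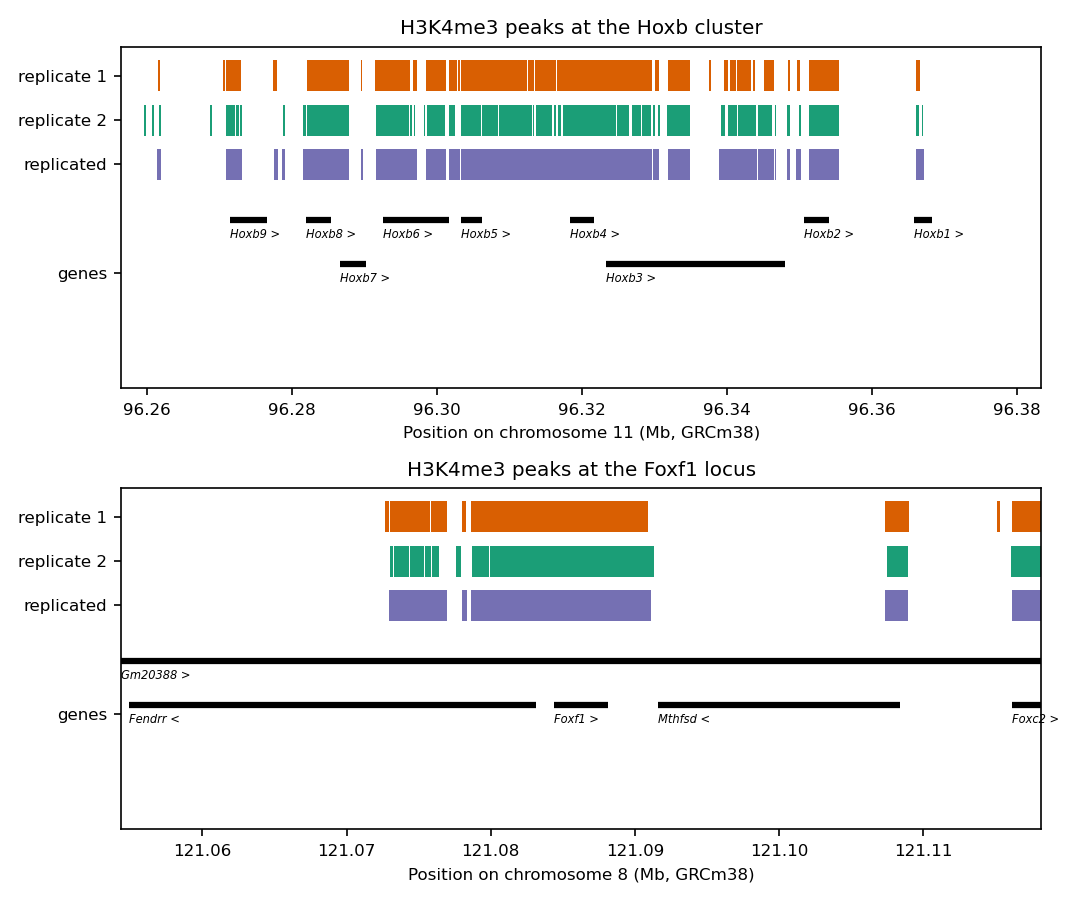
Blocks show the peaks of replicate 1, replicate 2 and the replicated set along chromosome 11 at the Hoxb cluster and chromosome 8 at the Foxf1 locus, in Mb of GRCm38, with gene spans as black bars and arrows for their strand. Peaks run almost without a break from Hoxb6 to Hoxb3, and a wide block covers Foxf1 in each set.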

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

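This result was looked for only after the chromosomes had been analysed, and no test was applied to it. The replicated set held 10 peaks on 5 scaffolds outside the assembled chromosomes, which no comparison used. All 10 overlapped peaks in both replicates. Their median signal was 7.38 and the widest measured 2191 bp. Of them, 6 lay within 1 kb of an annotated start, at Vamp7, a vesicle fusion gene, Tmlhe, a carnitine synthesis gene, and 3 genes known only by clone names. No technical or biological explanation was tested.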

How the results depend on the processing

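A peak in any of the 4 lists was the only alternative here chosen after the data had been seen, and the cause of a changed result was not tested except where stated. The number of marked genes stayed between 13731 and 14653 under all alternatives. With the annotated 5' end of the gene alone, 13697 of the 14380 genes were still marked. All 10 lists marked more often stayed so under every alternative except 2, namely the annotated 5' end of the gene and the CpG-rich background. Depth is unknown, so peaks missing from a list cannot be set against the reads behind it.

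With CpG-rich promoters alone, 0 lists were marked more often and 1 less often. Other genes there were marked at 98.8%, which leaves no room for a higher share, and several lists kept few members. Marking was 100% for epithelial transcription factors, junction, Wnt and stem cell, mesenchyme, Hedgehog, BMP and Notch, cell cycle and housekeeping genes, and on the other side of the other genes at 100% for enterocyte (1 of 1), blood (3 of 3), liver (3 of 3), stomach (1 of 1) and skeletal muscle (3 of 3) genes. Brain genes at 95.5%, Hox genes at 96.4% and ribosomal protein genes at 98.5% fell below the other genes, and cardiac genes stood at 83.3%. Width ratios on that background were 2.00 for blood, 0.691 for smooth muscle (both turned, 3 members each), 1.22 for cell cycle, 1.54 for endothelial, 1.41 for junction and 1.76 for mesothelial genes, with 3 lists narrower. The smooth muscle and cell cycle calls ended, and blood, endothelial, junction and mesothelial genes became wider.

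Brain genes were marked at 72.0% with the annotated 5' end of the gene. Cardiac genes reached 50% with the pooled list, with any of the 4 lists and with a window of 2.5 kb, and 40.0 to 45.0% in the replicates, and skeletal muscle genes 45.0% with 2.5 kb. Endothelial genes passed the test at 90.9% with the pooled list, 95.5% with any list, 85.7% without shared starts and 90.9 to 95.5% in the replicates. Enteric nervous system genes passed it at 88.0% with the pooled list and any list and at 84.0% without shared starts, with 80.0 to 88.0% in the replicates.

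Width ratios with the pooled list were 0.665 for blood, 0.842 for brain, 0.581 for cardiac, 0.847 for skeletal muscle, 1.45 for enteric nervous system, 1.33 for junction and 0.678 for secretory genes. Blood, cardiac and secretory genes thereby became narrower and enteric and junction genes wider, while the brain and skeletal muscle calls ended. Of the 5 narrower lists 3 stayed, and in all 6 were narrower and 11 wider. Secretory genes had 0.698 with a gap of 0.5 kb and 0.478 with unmerged peaks, and became narrower with both and in the list of replicate 1. With a gap of 2 kb enteric nervous system genes had 1.48 and became wider, and brain genes had 0.819 at percentile 3.87, which ended their call. Hox genes had 1.85 with unmerged peaks, 7.01 with a gap of 2 kb and 2.07 to 2.86 in the replicates, always wider, but their place among the lists changed. In the replicates' own lists the ratio was 0.780 to 0.947 for brain, 0.290 to 0.840 for skeletal muscle and 0.603 to 0.779 for secretory genes, and 3 to 6 lists were narrower. With unmerged peaks 8 of the 15 widest domains stayed, a change that follows from splitting them.

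Overlap of replicate 1 with 2 and of 2 with 1 was 73.0% and 65.2% for at least 50% of both peaks, 81.4% and 78.4% for 50% of either peak, 87.4% and 92.9% at a −log10 p of 5 or more, where 1573 peaks were found in replicate 2 only, and 82.4% and 87.8% for equal numbers of peaks. With width times signal Spearman rho was 0.893 and Pearson r 0.935, and with a window of 2.5 kb they were 0.747 and 0.869. By construction, a window of 2.5 kb moved peaks to starts (81.1%) and out of exons (2.90%), introns (5.59%) and regions outside genes (10.4%), and a window of 0.5 kb put 5.36% in exons and 11.98% outside genes. In the replicates' own lists 65.9 to 69.2% of peaks lay at starts, 5.27 to 5.74% in exons, 13.2 to 15.7% in introns and 12.3 to 12.8% outside genes, and 8044 to 9973 peaks were distal. Among 144 named genes, the state changed for Dppa3 with a window of 0.5 kb, for Muc2, Myf6, Nkx2-5 and Tbx5 with 2.5 kb and for none at the stricter −log10 p. The pooled list added Hoxc12, Nkx2-5, Otx2, Spdef, Tbx5 and Tie1, and any of the 4 lists added these and Nos3. The list of replicate 2 added Hoxc12, Nos3 and Tbx5 and lost Dppa3, and that of replicate 1 added Nkx2-5, Nos3, Spdef and Tie1 and lost Tdrd1. The annotated 5' end of the gene left Anpep, Dppa3, Egfl7, Krt19, Pecam1, Runx1 and Ywhaz unmarked.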

Other observations

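Chosen only after the data had been seen were the gene families, the noncoding RNAs, the matching of lists other than the enterocyte and brain lists on CpG content, and 4 of the tests below, namely CpG number at wide domains (both tests), any-list marking of enterocyte genes and signal at brain genes. Among 30 gene families named by their symbols, all 10 Frizzled receptors (adjusted p = 0.0305 by Fisher's exact test) carried the mark, with a median domain of 5137.5 bp. All 14 Eph receptors did so too (adjusted exact p = 0.00746), as did 18 of 19 Sox genes and 18 of 19 Wnt ligands (adjusted exact p = 0.0110 for each). The Fox family was marked at 37 of 44 genes and the collagens at 39 of 45, with Foxf2 and Col3a1 the widest. Canonical histone genes were marked at 58 of 67 with a median domain of 3771 bp, although these near-identical copies lie side by side. Complex I (Nduf) genes were marked at 45 of 46, proteasome subunits at 38 of 40 and zinc finger (Zfp) genes at 347 of 394. Families marked less often than other genes included keratins at 8 of 53, claudins at 12 of 33, cytochrome P450 genes at 25 of 100, interleukins at 6 of 33 and mucins at 2 of 12, namely Muc1 and Muc13. Defensins were marked at 0 of 64, bitter taste receptors at 0 of 35 and vomeronasal receptors at 1 of 329, Vmn1r4. Families that did not pass the test included the T-box genes at 9 of 13 (adjusted exact p = 1), Fgf ligands at 17 of 22 (0.395), Irx genes at 6 of 6 (0.127), Lhx genes at 7 of 8 (0.321) and nuclear receptors at 22 of 26 (0.0784). Pax genes did not pass either, at 8 of 9 (adjusted exact p = 0.215), and had narrow domains, with a median of 1282.5 bp at percentile 0.47 of random lists.

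Among noncoding RNAs, Malat1, an abundant nuclear RNA, had a domain of 8557.5 ± 429.2 bp (SD, n = 2) and Carmn, a smooth muscle RNA, of 9705.5 ± 2336 bp. The imprinted RNAs H19, Meg3, Kcnq1ot1 and Airn were marked, as was Xist, the RNA of the inactive X chromosome, at 3419 ± 265.9 bp. Hottip and Hotair, RNAs of the posterior Hox clusters, were unmarked. On the Y chromosome 4 of 183 genes were marked, namely Ddx3y, Eif2s3y, Kdm5d and Uty. The highest −log10 p of every list stood at Hjurp, a centromere chaperone gene, where it was 566 in the replicated set against 447 for the next peak. The signal there was 26.6, and 41.8% of replicated peaks had a higher one. No explanation was tested for any of these values.

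Wide domains at genes that pattern the gut may come from the number of CpGs around their starts, from the joining of peaks or from neighbouring genes under shared domains. Against random lists matched on the number of CpGs in 5 kb, the mesenchyme, epithelial transcription factor, Hox, and Hedgehog, BMP and Notch lists all stood at percentile 100. With unmerged peaks the lowest percentile of these lists and the Wnt and stem cell list was also 100, and with each domain counted once it was 99.99, with a median of 4502 bp over 29 domains of Hox genes. These values argue against the number of CpGs in 5 kb and joined peaks as the whole explanation for the first 4 lists. For Hox genes, with 38 marked members under 29 domains, they also argue against shared domains as the whole explanation. In the other lists each marked member had a domain of its own within the list. Counting each domain once could thus not change their medians, and it tested shared domains only for Hox genes. Joining still moved the Hox median from 3750.5 to 6338 bp. CpGs outside those 5 kb were not matched, although 23 of 38 Hox and 16 of 30 mesenchyme domains were wider than 5 kb, so they remain a candidate. Counting each domain once did not remove the dependence between neighbouring domains of a Hox cluster, so that value says less about Hox genes. The Wnt and stem cell list stood at percentile 79.4 after CpG matching (3224 bp against 2952 bp), so CpG number remains a candidate explanation there. Cell mixture and depth were not tested, and the design names no group that could give a biological explanation.

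Low marking of absorptive enterocyte genes may follow from CpG-poor promoters or from peaks lost when the replicated set was made. Of lists matched on observed over expected CpG, a mean of 6.90 members were marked, against the 7 found, at percentile 53.6. With a peak in any of the 4 lists, 7 of 22 were still marked against 67.1% of other genes (p = 0.000912 by Fisher's exact test), which argues against lost peaks. CpG content thus stays open as an explanation of this list, and no biological explanation was tested. Matched in the same way, smooth muscle genes were marked at 15 against a mean of 9.48, junction genes at 19 against 13.1, endothelial genes at 19 against 14.3 and mesenchyme genes at 30 against 24.995, all above the central 95% of matched lists, as were epithelial transcription factors at 20 against 16.7. Germline genes at 4 against 12.4 and stomach genes at 1 against 3.39 lay below it. Inside it lay several lists that differed from other genes by the unmatched test, namely blood at 7 against 6.80, liver at 5 against 6.03, cardiac at 7 against 9.19 and skeletal muscle genes at 6 against 7.98. Wnt and stem cell genes at 23 against 21.9 and Hox genes at 38 against 35.9 equalled its upper limit, at percentiles 86.6 and 92.3. CpG content stays open for the calls of these 6 lists as well. Ribosomal protein genes at 73 against 74.2 lay inside the central 95% of matched lists (percentile 15.4), so CpG content stays open for their call too. The olfactory receptor list was not matched for marking. All cell cycle, housekeeping, and Hedgehog, BMP and Notch genes were marked, and the upper limit was the size of each list. No count could exceed that limit, so it decides nothing for these lists, which stood at percentiles 73.3, 77.0 and 97.7.

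Frequent marking of brain regionalisation genes in intestine may also follow from CpG-rich promoters. The 23 marked members compare with a mean of 23.1 in lists matched on observed over expected CpG, at percentile 45.35, so CpG content stays open as an explanation of how often they were marked. Their median signal was 11.8, against 36.5 in matched marked genes, at percentile 0 of 10000 lists. This shows only that peak signal was lower there than at starts matched on observed over expected CpG in 1 kb. The number of CpGs in 5 kb and GC content were not matched for signal. The signal is no test of why the genes were marked. No biological explanation was tested. Signal was low against matched genes for enteric nervous system genes too (9.61, percentile 0) and for Hox (16.7, percentile 0), secretory (9.16, percentile 0), germline (8.05, percentile 0.03), pancreas (11.4, percentile 0.05), epithelial transcription factor (16.8, percentile 0.13), cardiac (10.5, percentile 0.15) and endothelial genes (11.6, percentile 0.16). The same held for enterocyte (6.97, percentile 0.38), Wnt and stem cell (27.8, percentile 0.59), mesothelial (14.01, percentile 1.01), skeletal muscle (11.3, percentile 1.01) and junction genes (14.99, percentile 1.665). A low level was thus not particular to brain genes, but it was not found for every list. Signal lay inside the central range of matched lists for mesenchyme (30.6, percentile 43.75) and cell cycle genes (36.9, percentile 56.7). So it did for blood (22.6, percentile 30.5), liver (22.9, percentile 18.9) and smooth muscle genes (12.6, percentile 7.93). Olfactory receptor (5.04, percentile 6.09) and Hedgehog, BMP and Notch genes (30.3, percentile 5.385) lay inside it too. Housekeeping (44.6, percentile 99.99) and ribosomal protein genes (45.3, percentile 100) lay above it.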
